A study of Caenorhabditis elegans with 2 samples.

How the data were processed

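The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caenorhabditis elegans. Whole late embryos, collected 5 h after synchronization by egg bleaching, carried an integrated transgene that expresses GMEB-2 with a C-terminal GFP-FLAG tag. GMEB-2 is a worm relative of the vertebrate glucocorticoid modulatory element binding proteins. The strain has an unc-119 mutation and the transgene insertion wgIs622. Chromatin was sheared by sonication, and an antibody against GFP was used for the precipitation, per the labels. The 2 samples were biological replicates 1 and 2 of 1 group, so no comparison between conditions was possible. Replicate 2 lists 2 sequencer models in its labels and replicate 1 lists none.

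Peaks were deposited as lists on builds ce11 and ce10. Per the labels and the listing that accompanied the lists, the authors made a relaxed list of peaks and background for each replicate alone, a relaxed list for both replicates together, and a list thresholded by irreproducible discovery rate (IDR), which ranks peaks by their agreement between replicates. Peaks were therefore called both per sample and on pooled samples, each time against a control alignment. The peak caller, the aligner, the handling of reads with several matches and the IDR threshold are not given in the sources used here. Each deposited peak carries a signal value, which is the authors' own value for that peak against the control. Each deposited peak also carries a -log10 q value, which was not tested further. Signal values were used only to rank and describe peaks within a list, since each list has its own scale. Read counts and sequencing depth are unknown, so no interval was computed from depth.

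Signal was ranked from high to low, and positions are 1-based on ce11. Genes came from the Ensembl 115 annotation of WBcel235, the same assembly as ce11, and tRNA isotypes from the RefSeq annotation. ce10 lists were used only for counts and overlap, since no ce10 annotation was used here. The main set was the IDR list on ce11. A peak was shared between replicates when the summits lay within 200 bp. A gene was a target when a summit lay from 1000 bp upstream to 500 bp downstream of its annotated 5′ end. A peak was near a tRNA or snoRNA gene when its summit lay within 200 bp of the gene body, and peaks near both were counted at the tRNA gene. The nearness of peaks to tRNA and snoRNA genes, the B box words, the tests without these peaks, the isotype test, the GC-matched controls and the shifted shares by rank were chosen after the data were seen. The promoter, chromosome, gene list, gene biotype, motif and transgene tests, with the list members, were fixed before the data were examined.

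Replicate overlap, promoter location, divergent promoters and transgene loci were tested with 10000 circular shifts of the summits within each chromosome. The smallest p these can give is 1e-04 one-sided and 2e-04 two-sided. Differences in median signal and correlations across peaks used 100000 permutations, whose smallest p is 1e-05. Gene lists and gene biotypes with at least 20 nuclear genes were tested with two-sided Fisher's exact tests, and chromosomes with exact binomial tests against their share of protein-coding genes. All families of tests were adjusted by the Benjamini-Hochberg method at 0.05. Intervals are 95% exact Clopper-Pearson intervals over genes or windows. They treat genes as independent, although neighbouring genes can share a peak. The 29 gene lists comprised cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, mitochondrial import, the proteasome, translation factors, aminoacyl-tRNA synthetases, splicing, chaperones, endoplasmic reticulum folding, the vacuolar ATPase, autophagy, ubiquitin conjugation, histones, chromatin regulators, the cell cycle, homeobox factors, nuclear hormone receptors, GATA factors, collagens, muscle, pharynx, intestine, epidermis, neuron and germline markers, chemoreceptors, C-type lectins and the GMEB family.

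Words were counted on both strands in windows of 201 bp around the summits of promoter peaks. Each had 10 control windows at the same offset from the 5′ end of random protein-coding genes, with no summit of the 5000 strongest peaks of the relaxed joint list within 500 bp. All 2080 words of 6 bases were tested, and TACGTA was the core word of the vertebrate proteins. A second control set was also matched for GC content. The B box, the internal promoter element that binds TFIIIC at tRNA genes, was searched as GWTCRANNC in IUPAC code. Sequence uniqueness was the share of 36-base words that occur once in the nuclear genome, counting both strands.

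The text names the genes at the 25 peaks with the highest signal, gmeb-1 to gmeb-4 and unc-119, and up to 4 targets of highest signal for each list past the threshold or with at least 3 targets. It also names the 10 words with the smallest p. Genes and peaks outside this rule were named after their values were seen. On simulated peaks, with a 10-fold weight on 1 list over 19973 genes, the gene list test recovered that list in 39 of 40 runs and called 3 of 1120 other lists. The simulated genes were drawn independently, with equal weight outside that list of 70 members. Observed folds of the enriched lists were lower, from 3.99 to 8.43, so these rates need not hold for the real peaks. The promoter test called 0 of 40 sets of random peaks; detection of a planted promoter excess was not simulated. The word scan ranked a word planted in 20% of 321 windows first in 10 of 10 runs. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives covered the summit distance, the promoter window, the peak set, each replicate's own list, the control windows, the words, and the distance to the transgene loci.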

Results

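Binding of GMEB-2-GFP was mapped by ChIP-seq in late embryos of Caenorhabditis elegans, in 2 biological replicates of 1 strain. Each replicate's relaxed list held 30000 peaks, as did the list of both replicates together. The IDR list held 634 peaks on ce11, with authors' signal values from 91.8 to 1083 and a median of 135. These 634 peaks were the same intervals as the 634 strongest peaks of the joint relaxed list. The lists gave no read counts, so the depth is unknown.

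The first comparison was between the replicates. Of the 634 strongest peaks of replicate 1, 427 (67.4%, 95% exact interval 63.5% to 71.0%) had a summit of replicate 2's strongest 634 within 200 bp, against a mean of 1.70 in shifted data (circular-shift permutation test, one-sided p = 1e-04, the smallest possible). IDR uses agreement between replicates, so the presence of its peaks in both lists is not a test of agreement. Since the IDR list is the top of the joint list by signal, its peaks need not each agree between replicates. The median rank of the IDR peaks was 322 in replicate 1 and 314.5 in replicate 2, and the worst ranks were 23508 and 5209. Of the 634 peaks, 423 were within the top 634 of both replicates. Across the 631 peaks seen in both, log2 signal gave Spearman's rho = 0.702 and Pearson's r = 0.808 (permutation p = 1e-05 for each, the smallest possible). Without the peaks at tRNA and snoRNA genes, rho was 0.523 and r was 0.673 (permutation p = 1e-05 for each). These correlations run across peaks, which are not independent replicates. The peaks were also selected by joint signal, which can itself change the correlations. The lower values without peaks at tRNA and snoRNA genes therefore need not mean weaker agreement there. The joint list came from both replicates together. Of its peaks, 99.5% of ranks 1 to 634 had a summit in both replicate lists, against 57.6% of ranks 5001 to 10000 and 8.10% of ranks 20001 to 30000. Means in shifted data were 3.87%, 3.92% and 3.87%.

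**Figure D1:**
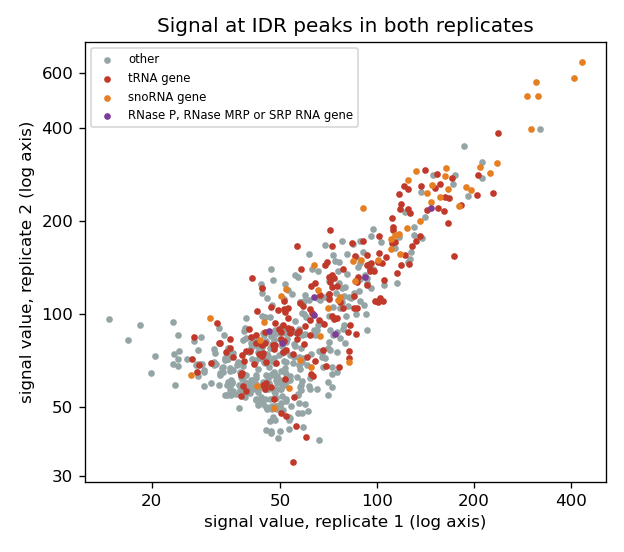
Authors' signal value at each IDR peak in replicate 1 (x, log axis) and replicate 2 (y, log axis), coloured by what lies within 200 bp of the summit, for the 631 peaks with a value in both. The peaks at snoRNA genes reach the highest values in both replicates, and rho was 0.702.

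The strongest peaks lay at genes for small noncoding RNAs. Of the 25 peaks with the highest signal, 13 were within 200 bp of a small nucleolar RNA (snoRNA) gene and 5 within 200 bp of a tRNA gene. SnoRNAs guide the chemical modification of ribosomal and other RNAs. All 25 ranked within the top 100 of both replicates. The strongest peak (chromosome II, 11960653 to 11961010, intergenic) had a signal of 1083 and its summit 74 bp upstream of the 5′ end of the snoRNA gene W03C9.9. It ranked 1 in both replicates. The second (V, 12303447 to 12303816, signal 995) lay inside the snoRNA gene C51F7.4, in an intron of frm-7. The third (V, 8500407 to 8500722, signal 861) lay 4 bp upstream of ZK994.7, in an intron of pxn-1. The fourth (I, 8259380 to 8259738, signal 826) lay 62 bp upstream of ZK265.10 and in the promoter window of the chemoreceptor gene sre-23. The fifth (V, 15873780 to 15874156, signal 803) lay 49 bp upstream of T06C12.16, with nhr-102 the nearest protein-coding gene.

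Further snoRNA genes with a peak among the top 25 were T03F7.8 (nearest protein-coding gene cutl-18), T02E1.9 (T02E1.2), H09I01.2 (K07H8.7), C04G6.12 (mpk-2), B0334.12 (twk-5), C27H6.5 (unc-41), D1046.6 (cfim-2) and F32E10.10 (clec-180), with signals from 441 to 701. The tRNA genes were 1 for tRNA-Leu near C04A11.5 (X, 13665427 to 13665737, signal 630), 1 for tRNA-Ala in an intron of him-4 (X, 9743455 to 9743764, signal 477), and 3 for tRNA-Ile. The latter lay in an intron of col-85 (II, 12494618 to 12494882, signal 479), near ets-5 (X, 5085543 to 5085775, signal 455) and upstream of gcy-33 (V, 12002075 to 12002320, signal 450). The other 7 peaks lay upstream of K12H4.5 (III, 8043824 to 8044109, signal 716), atx-2 (III, 10461174 to 10461456, signal 516), T13C5.6 (signal 492), ears-2 (signal 455), rpl-3 (III, 3867460 to 3867702, signal 436) and M01F1.9 (signal 435), and at the noncoding gene F36H1.17 near alh-3 (IV, 11025916 to 11026357, signal 544). The summit upstream of T13C5.6 was also inside the noncoding gene C14F11.14. That near M01F1.9 was 968 bp upstream of it and in an intron of M01F1.8. The gene atx-2 encodes an ataxin-2 relative, and rpl-3 a protein of the large ribosomal subunit.

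Over the whole IDR list, 187 peaks (29.5%) lay within 200 bp of a tRNA gene and 51 within 200 bp of a snoRNA gene. Shifted data gave a mean of 1.92 and 1.16 (circular-shift permutation test, one-sided p = 1e-04 for each, the smallest possible). In 140 peaks the summit was inside the tRNA gene itself. Median signal was higher by 38.7 at tRNA genes, where it was 163, and by 165 at snoRNA genes, where it was 294, each against all remaining peaks (permutation test, two-sided p = 1e-05 for each, the smallest possible). Another 7 peaks lay at RNA genes of other known complexes: rpr-1 (RNase P RNA, signal 365), mrpr-1 (RNase MRP RNA, signal 217) and the signal recognition particle RNA genes srpr-1.1, srpr-1.2, srpr-2.1 and srpr-2.2. Among the 64 strongest peaks 42.2% were at tRNA genes and 35.9% at snoRNA genes. Among the 63 weakest these shares were 9.52% and 1.59%.

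**Figure D2:**
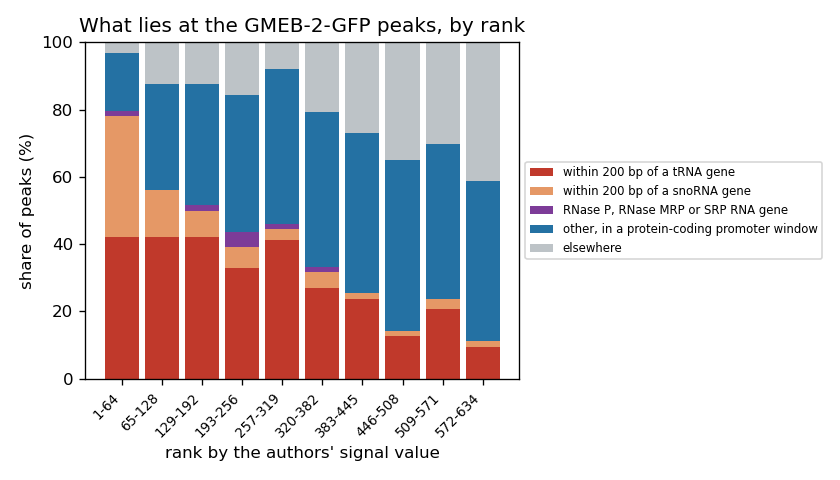
Share of IDR peaks (y, %) by what lies at the summit, in 10 bins of rank by the authors' signal value (x). The tRNA share falls from 42.2% in the first bin to 9.52% in the last, and the snoRNA share from 35.9% to 1.59%.

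Counted by gene, 36.1% of the 612 nuclear tRNA genes (95% exact interval 32.3% to 40.1%) and 58 of 346 snoRNA genes (16.8%, 13.0% to 21.1%) had a summit in the window around the 5′ end. This was 15.4 and 7.17 times the share over all nuclear genes (Fisher's exact test, adjusted p = 4.47e-201 and 1.79e-31). The annotated class of other noncoding RNAs reached 312 of 7764 genes (1.72 times, Fisher's exact test, adjusted p = 7.47e-23). Genes of piRNAs (33 of 15363) and pseudogenes (8 of 2128) were targets less often, at 0.0918 and 0.161 times (Fisher's exact test, adjusted p = 2.54e-138 and 2.8e-13). The share over all 46890 nuclear genes includes the piRNA genes, which lower it. The folds and tests of the other classes, protein-coding genes among them, therefore depend on the piRNA genes. Values for miRNA genes (10 of 261, adjusted p = 0.214), snRNA genes (7 of 129, 0.0594), long intergenic RNAs (2 of 194, 0.411), antisense RNAs (2 of 100, 1), rRNA genes (0 of 20, 1) and protein-coding genes (444 of 19973, 0.214) did not pass Fisher's exact test. The snRNA genes passed it in all 6 alternative settings, at 2.47 to 2.88 times (exact test, adjusted p from 0.00724 to 0.0486). Each of these settings kept the piRNA genes in the background, so whether snRNA genes exceed the classes other than piRNA was not tested. No tRNA isotype had a share of genes with a peak that passed the test. Raw p was lowest for tRNA-Glu (19 of 41, Fisher's exact test, p = 0.0604, adjusted p = 1).

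The position of the summit differed between the 2 kinds of gene. At tRNA genes the median summit was 15 bp downstream of the annotated 5′ end (quartiles 4 and 42 bp). At snoRNA genes it was upstream, at a median offset of -47 bp (quartiles -58.5 and -25.5 bp), and 48 of 51 summits lay upstream. The B box word was present in 96.3% of windows at tRNA genes, 60.8% at snoRNA genes, 7.46% at the other 389 peaks and 8.99% of 1268 flanking windows. The B box is internal to tRNA genes, and the first windows were chosen for nearness to one. Their share follows largely from that choice and is not evidence on binding. Of 48 snoRNA genes with this word on their own strand in the 200 bp upstream, 27 (56.3%) had a summit within 200 bp. Of 298 without it, 25 (8.39%) had one (Fisher's exact test, p = 1.67e-13).

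**Figure D3:**
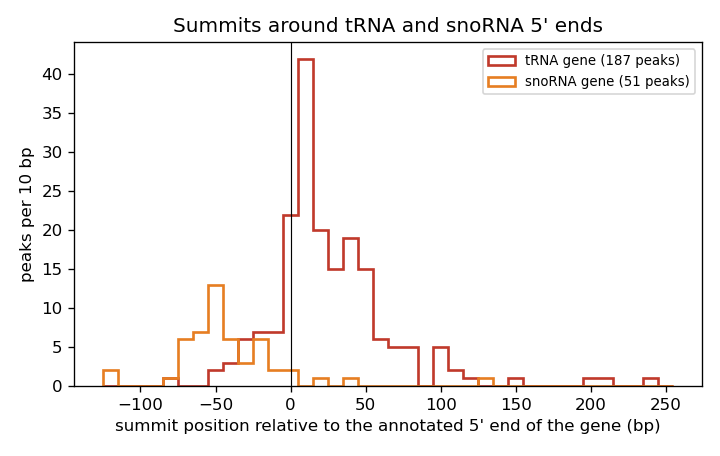
Number of IDR peak summits per 10 bp (y) by position relative to the annotated 5′ end (x, bp, negative upstream) for the 187 peaks at tRNA genes and the 51 at snoRNA genes. The tRNA summits centre at 15 bp and the snoRNA summits at -47 bp.

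Promoters of protein-coding genes held a summit for 321 of 634 peaks (50.6%), against a mean of 25.7% in shifted data (circular-shift permutation test, two-sided p = 2e-04, the smallest possible). These peaks gave 444 target genes. Of the 321, 107 (33.3%) lay in promoter windows on both strands, against 10.4% in shifted data (permutation test, two-sided p = 2e-04, the smallest possible). By annotation, 409 summits were intergenic, 190 in introns, 18 in coding exons, 13 in 5′ UTRs and 4 in 3′ UTRs of protein-coding genes. Median signal was 133 in promoter windows and 137 elsewhere (permutation p = 0.607). Without the peaks at tRNA and snoRNA genes the difference turned to 13.7 higher in promoter windows (permutation p = 0.00494).

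Of the 29 gene lists, 7 passed the test with more targets than expected, among them lists for protein synthesis, mitochondria, chaperones and splicing. The background was all 19973 protein-coding genes, whatever their activity in embryos. Lists of another factor or an untagged strain were not used, so whether these lists are particular to GMEB-2 was not tested. Of 81 cytosolic ribosomal protein genes 13 were targets (95% exact interval of the share 8.83% to 25.9%), 7.22 times the expected number (Fisher's exact test, adjusted p = 7.5e-07). Against shifted peaks in place of Fisher's test, the 7 lists gave higher folds, from 9.19 times for chromatin regulators to 19.1 times for mitochondrial import, with ribosomal proteins at 16.5 times (circular-shift permutation test, adjusted p from 0.00116 to 0.00249). Shifted summits lose the preference of the peaks for promoters (50.6% of peaks against 25.7% in shifted data). The higher folds therefore include that preference and are not particular to the lists. The strongest ribosomal protein genes were rpl-3 (signal 436), rpl-15 (279), rpl-20 (232) and rps-20, with summits 247 to 345 bp upstream of the 5′ end. Translation factors gave 5 of 40 (5.62 times, exact test, adjusted p = 0.00776), among them the initiation factor subunit genes eif-3.C and eif-3.D and the elongation factor genes eef-1A.1 (signal 131) and eef-2. Splicing factors gave 6 of 51 (5.29 times, exact test, adjusted p = 0.00523), with snr-1 (signal 242), prp-19 (144), lsm-3 (133) and rsp-1 and rsp-2 sharing 1 peak (117).

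Chaperone and heat shock genes gave 9 of 60 (6.75 times, exact test, adjusted p = 6.4e-05), led by dnj-29 (signal 226), hsp-60 (199), hsp-1 (154) and dnj-13 (137). Oxidative phosphorylation gave 8 of 70 (5.14 times, exact test, adjusted p = 0.00115). These included ndua-2 (226, the peak shared with dnj-29), cox-5B (160), cox-5A (118) and cyc-1 (116). Mitochondrial import and chaperones gave 3 of 16, namely ddp-1 (238), hsp-60 and tomm-20 (113) (8.43 times, exact test, adjusted p = 0.0179). Chromatin regulators gave 7 of 79 (3.99 times, exact test, adjusted p = 0.00776), led by swsn-3 (176), lin-35 (166), cbp-1 (165) and jmjd-1.2 (133). With each peak given only to its nearest 5′ end, 3 of these 7 lists passed the test. Mitochondrial import (7.90 times, adjusted p = 0.125), translation factors (4.74 times, 0.125), chromatin regulators (3.20 times, 0.152) and splicing factors (2.48 times, 0.56) then did not (Fisher's exact test). With the 317 strongest peaks alone, ribosomal proteins and chaperones passed, while translation factors (2.30 times, adjusted p = 0.856), oxidative phosphorylation (2.63 times, 0.594), splicing factors (3.61 times, 0.513), chromatin regulators (3.50 times, 0.318) and mitochondrial import (11.5 times, 0.0925) did not (exact test). Mitochondrial import was also lost without replicate 2 (6.18 times, exact test, adjusted p = 0.131) and with a window of 500 bp to either side (7.39 times, 0.0944).

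Chemoreceptor genes were targets less often, with 7 of 1299 (0.539%, 0.242 times the expected number, Fisher's exact test, adjusted p = 1.81e-05). Their strongest peaks were those near sre-23 (signal 826, at a snoRNA gene), sre-1 (287), srh-269 (188, at a tRNA gene) and sri-5 (160). Against shifted peaks the chemoreceptor value was 0.741 times the mean (circular-shift permutation test, adjusted p = 0.856). Lists that did not pass Fisher's exact test but had at least 3 targets were mitochondrial ribosomal proteins (mrpl-23, mrpl-39, mrpl-12 and mrps-25; 4 of 66, adjusted p = 0.172), histones (5 of 72, adjusted p = 0.0709, with his-67 and his-68 sharing 1 peak, then his-37, and his-31 with his-32 at a further one), nuclear hormone receptors (nhr-255, nhr-47 and nhr-48; 3 of 274, adjusted p = 0.658) and cuticle collagens (col-85, col-185 and col-71; 3 of 176, adjusted p = 1). Against shifted peaks histones and mitochondrial ribosomal proteins passed the test (circular-shift permutation test, adjusted p = 0.0316 and 0.0275), and histones also without the peaks at tRNA and snoRNA genes (Fisher's exact test, adjusted p = 0.0375). Shifted summits lose the preference of the peaks for promoters, so the shift results for these lists and for chemoreceptors include it. The peaks at nhr-255, col-85 and col-185 were at tRNA genes.

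No list of tissue markers passed the test in either direction. No target was found among 37 body wall muscle, 22 pharynx, 32 intestine and 21 epidermis markers, 88 homeobox genes, 12 GATA and endoderm genes, 33 proteasome genes and 3 GMEB family genes. Neuron markers (1 of 35), germline markers (1 of 32), cell cycle genes (2 of 63), C-type lectins (2 of 240), aminoacyl-tRNA synthetases (1 of 32), endoplasmic reticulum folding genes (1 of 17), vacuolar ATPase genes (1 of 20), autophagy genes (1 of 28) and ubiquitin conjugation genes (1 of 27) did not pass Fisher's exact test (adjusted p from 0.484 to 0.901). With 0 of 37 genes the exact interval reached 9.49%, so the small lists exclude only large shares.

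**Figure D4:**
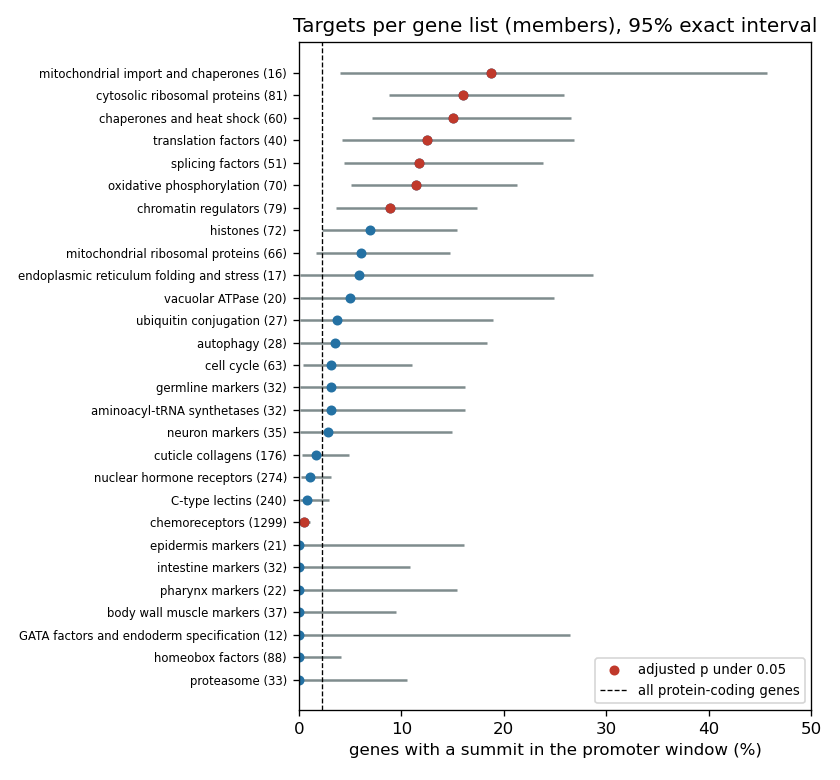
Share of each list's genes with an IDR summit in the promoter window (x, %), with 95% exact intervals as lines, for lists of at least 10 members (number in parentheses). Red points passed the test at an adjusted p under 0.05, the GMEB family with 3 members is not drawn, and the dashed line is the share over all protein-coding genes, 2.22%.

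The word TACGTA, the core of the vertebrate GMEB site, was not more frequent at the peaks. It stood in 3 of 321 promoter peak windows (0.935%, 95% exact interval 0.193% to 2.71%) and in 62 of 3210 controls (1.93%; Fisher's exact test, odds ratio 0.479, p = 0.276). Its 21 occurrences within 250 bp of an IDR summit had a mean distance of 139 bp, against a smaller mean for uniform positions (permutation test, one-sided for closer, p = 0.837). The words with the smallest p were GC-rich: ACGCGC (24.0% of windows against 2.87% of controls, Fisher's exact test, adjusted p = 4.21e-35), GCGCAC (25.2% against 3.43%), CGCGCA (23.7% against 3.36%), CGCAAG (21.8% against 2.83%), GCACGC, CGCACA, GCGCGC, CCGCAC, AACGCG and GCGCAA. Peak windows had a mean GC content of 43.9% and controls 34.6%. With controls also matched for GC content (42.8%) all 10 words still passed the test, and the number of words more frequent at the peaks fell from 487 to 242.

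Chromosomes X and III held more peaks than their share of protein-coding genes. X had 146 peaks against 86.7 expected (1.68 times, exact binomial test, adjusted p = 1.21e-09), and III had 19.4% of the peaks against 13.2% expected (1.47 times, adjusted p = 2.62e-05). By the same exact binomial test, V had 95 against 159 expected (0.599 times, adjusted p = 3.39e-09), IV had 80 (0.768 times, adjusted p = 0.0129), II had 87 (0.795 times, adjusted p = 0.0215) and I had 103 (1.13 times, adjusted p = 0.193). Without the peaks at tRNA and snoRNA genes, X had 60 peaks (1.11 times, exact binomial test, adjusted p = 0.38) and III had 93 (1.78 times, adjusted p = 1.66e-07). The values for II and IV did not pass the test in either replicate's own list. Against the share of assembled length in place of genes, X gave 1.30 times and III 1.41 times (exact binomial test, adjusted p = 0.00116 and 0.000496).

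The loci of the tagged gene and of unc-119, taken to be in extra copies in the strain, held no IDR peak. Within 20 kb of gmeb-2 (X, 15879085 to 15885626) and of unc-119 (III, 10902641 to 10908935) the count was 0, against means of 0.389 and 0.424 in shifted data (permutation test, one-sided p = 1 for each). No IDR summit lay in the promoter window of gmeb-1 (II, 19538 to 22169), gmeb-2, gmeb-3 (III, 3768500 to 3770328) or unc-119. The relaxed joint list had a summit 572 bp upstream of gmeb-1, at rank 1240 with a signal of 72.1. The annotation used here had no gene under the symbol gmeb-4.

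On ce10 the IDR list also held 634 peaks. Per chromosome, I and II had the same counts on both builds, and X had 147 on ce10 against 146 on ce11. The largest difference was on III, with 117 on ce10 and 6 more on ce11.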

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

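The tests of sequence uniqueness at tRNA genes and around gmeb-2 and of the flanks of gmeb-2 were set down before their results were seen. The comparison with ribosomal protein genes, the search for another factor's list, the uniqueness at snoRNA genes and both tests on X were chosen afterwards, as was the choice of the patterns. The design has 1 group and names no biological explanation to set against the technical ones, so none from the design was tested.

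The relaxed joint list held a signal at tRNA genes beyond the IDR list. Of the 411 tRNA genes without an IDR summit within 200 bp, 48.9% had a relaxed summit there, against a mean of 12.7% and a maximum of 19.2% in shifted data (circular-shift permutation test, one-sided p = 1e-04, the smallest possible). Together 402 of 612 tRNA genes (65.7%) had a summit at either level.

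For the peaks at tRNA and snoRNA genes, high transcription in general stays open, since transcription was not measured here. A summit in the promoter window was more frequent at tRNA genes than at cytosolic ribosomal protein genes (odds ratio 2.96, Fisher's exact test, p = 0.000248), but both kinds of gene are highly transcribed, so this does not decide it. At snoRNA genes the median share of unique 36-base words in the peak windows was 100%, which argues against reads collapsed onto repeated copies there. At the peaks near tRNA genes this median was 76.1%, so such reads stay open there. The share of tRNA genes with an IDR peak was 28.9% among the 204 with the least unique sequence, 39.2% in the middle and 30.4% among the 204 with the most. The ends differed by 1.47 percentage points (permutation p = 0.796), which does not decide it. Shares with a relaxed summit were 56.9%, 74.0% and 66.2%. The middle genes had 88.4% to 90.1% unique words and the most unique 90.1% to 100%, so these groups differ little in uniqueness. A signal that any tagged protein gives at these genes also stays open, since 0 lists of another factor or an untagged strain were used here.

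The excess of peaks on X may follow from the position of the tRNA genes, 45.1% of which are on X. Without the peaks at tRNA genes, X had 0.998 times its expected number (exact binomial p = 1). The expected number followed the share of protein-coding genes, and this value was not recomputed against assembled length. By length, all IDR peaks gave 1.30 times on X (exact binomial test, adjusted p = 0.00116). More frequent binding of the X tRNA genes is argued against as the whole cause, since 33.7% of them had a peak (95% exact interval 28.1% to 39.6%) and the excess would need 53.6%. The odds ratio against autosomal tRNA genes was 1.07 (Fisher's exact test, p = 0.729). Without the peaks at tRNA genes, chromosome III had 1.68 times its expected number (exact binomial test, adjusted p = 1.58e-06) and chromosome I newly passed the test at 1.29 times (adjusted p = 0.0303), while II and IV did not pass. With the peaks at snoRNA genes also left out, chromosome I did not pass (1.24 times, exact binomial test, adjusted p = 0.0795).

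Few relaxed summits lay around gmeb-2, with 1 within 20 kb against a mean of 11.9 in shifted data (permutation test, two-sided p = 0.0188, for 1 of 2 loci looked at). Sequence in which reads cannot be placed is argued against, since unique words made up 96.6% of it, at percentile 38.8 of windows of that size on X. Whether extra copies of the transgene in the control lower the signal there was not decided. The flanks from 20 to 60 kb held 19 summits, within the range of 95% of shifts and at a density 11.1 times that inside. The density inside rests on 1 summit, so any flanks within that range would exceed it. The flanks therefore show only that the low count is local. Whether the control came from the same strain is not given in the sources used here. At unc-119, taken to be in the transgene as well, the relaxed count was not low, at 25 against a mean of 18.3 (permutation p = 0.382).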

How the results depend on the processing

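No paired analysis was possible because there was 1 group. The 634 strongest peaks of the joint list were not run as a separate set for promoter location, chromosomes, gene lists, noncoding genes and TACGTA, since they are the IDR list itself. The settings without peaks at tRNA or snoRNA genes, with GC-matched controls and with gene bodies were chosen after the data were seen. Leaving out peaks within 20 kb of gmeb-2 or unc-119 removed 0 peaks, so the 19 values of that setting could not change. Of the other 202 recomputed values, 163 kept their direction and side of the threshold or stayed within 1.5 times the main count. Replicate overlap ranged from 48.8% to 78.9% and promoter location from 41.3% to 65.7%. Without peaks at tRNA or snoRNA genes, the signal difference by location turned from -3.77 to 13.7 (permutation p = 0.00494), 2 chromosomes passed the test in place of 5, and X gave 1.11, IV 0.753 and II 0.834 times the expected number. With the 317 strongest peaks 3 chromosomes passed, II gave 0.913 and IV 0.768 times, and 2 gene lists were enriched in place of 7. Nearest 5′ ends alone left 3 lists. The enriched lists rose to 9 in the shift test, 9 with the longer promoter window and 8 without peaks at tRNA or snoRNA genes, and the shift test left 0 lists below expectation in place of 1. The shift test does not hold the preference of the peaks for promoters fixed. Against assembled length II gave 0.901 times, and X 1.30 times in place of 1.68 (exact binomial test, adjusted p = 0.00116). Leaving out 1 replicate gave 3 chromosomes in both cases, from 0.886 to 0.932 times on II and from 0.816 to 0.835 times on IV. Enriched noncoding classes numbered 5 without replicate 1 and 4 without replicate 2 and in the other 4 settings, in place of 3, with snRNA genes past the threshold in each. The piRNA genes stayed in the background of each setting. The word ACGT was less frequent at peaks (odds ratio 0.771, Fisher's exact test, p = 0.0438) and GC-matched controls gave 242 enriched words in place of 487. The causes of these changes were not tested. Unknown depth limits what an absent peak shows.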

Other observations

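Peaks at some snoRNA genes lay in introns of protein-coding genes, for example C51F7.4 in frm-7, ZK994.7 in pxn-1 and C04G6.12 in mpk-2. Of the 51 peaks at snoRNA genes, 14 lay in a protein-coding promoter window, against 259 of the 389 peaks away from tRNA, snoRNA and related RNA genes. Peaks at RNase P, RNase MRP and signal recognition particle RNA genes had a median signal of 164 and no B box word in their windows. Of 7 snoRNA genes with the stricter B box word in the 200 bp upstream, 6 had a peak. None of the 20 annotated rRNA genes was a target, but the exact interval reached 16.8%, so this excludes only large shares.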
